A study of Mus musculus with 4 samples.

How the data were processed

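Total RNA from mouse small intestine was extracted with a Qiagen miRNeasy kit and labelled with the dye Hy5 using Exiqon's miRCURY LNA kit, per the labels' protocols. Each of 4 arrays held 1 sample in 1 colour, pooled from 3 mice. The groups, taken from the sample titles, were Tlr3+/+ and Tlr3-/- at 0 hr without treatment and at 6 hr after 10 Gy, with 1 array each. The scanner, the quantification software and the maker of the array are not given in the sources used here.

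For every array the authors deposited the raw intensity of 3136 spots, among them 1135 miRNA probes and 1818 blank spots. The deposited files also give a background-subtracted intensity and a globally normalized intensity, per the file headers. Compared with the raw values, the authors' background-subtracted column equals the raw intensity minus 1 constant per array, which is the mean of the blank spots with 5% left out at each end. The authors' normalized intensity is that value times 1 factor per array, which sets the median of the filled probes to 25 on every array. Cells are empty for probes at or below the blank mean plus 2 SD, a rule that gave 0 differences from the authors' filled cells. The authors' series value table equals the normalized column within 0.005, on a linear scale and with no centring of miRNAs. A coefficient of variation for repeated control spots is also in the deposited files and was not used.

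Values used here started from the raw intensity. The blank spots served as negative controls for a normexp background correction with an offset of 50 (function nec of limma 3.58.1, R 4.3.3), followed by quantile normalization over the 1135 miRNA probes and log2. The offset shrinks ratios of dim probes, so their log2 ratios understate changes. Quantile normalization gives probes of equal rank the same value, so some miRNAs, bright or dim, have a ratio of exactly 0. Of the miRNA probes, 1096 are of mouse, 12 of which name several miRNAs, and 39 are of viruses (29 mouse cytomegalovirus, 10 murine gammaherpesvirus). The viral probes entered the normalization and no comparison. A miRNA was detected on an array when its raw intensity passed the blank mean plus 2 SD, which was 25.8 for Tlr3+/+ at 0 hr, 26.5 for Tlr3-/- at 0 hr, 26.1 for Tlr3+/+ at 6 hr and 29.2 for Tlr3-/- at 6 hr. Each miRNA has 1 probe spot, and the only repeats are control spots. The 8 spots of each of 2 spike controls had a pooled SD of 0.104 on the log2 scale, a technical spread within arrays that leaves out the spread between mice, pools and arrays.

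Each of 4 pairwise comparisons gave the log2 ratio of 2 arrays for miRNAs detected on both, with no test, and miRNAs at or beyond 2-fold were counted. The difference of the irradiation ratios was computed for the 573 miRNAs detected on all 4 arrays. A limma fit with terms for genotype and irradiation, with 1 residual degree of freedom, eBayes and Benjamini-Hochberg adjustment, was run on 797 miRNAs detected on at least 2 arrays. Its p-values test the averaged change against a spread that is the disagreement between the genotypes, not a spread between replicate pools. The text names the 10 highest and 10 lowest ratios of each comparison, the 5 highest and 5 lowest differences, and members of fixed lists. miRNAs outside that rule, among them those that complete a count, were chosen after their values were seen.

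Fixed lists numbered 15: p53-responsive, intestinal epithelium, smooth muscle and stroma, striated muscle, leukocyte, red cell, pancreas and liver, neuron, miR-17~92 and related clusters, let-7, miR-30, miR-15/16, miR-29, DNA damage, and innate immunity (Toll-like receptor and NF-kB signalling). Lists were taken from general knowledge and some share members, such as miR-192 in the p53-responsive and epithelial lists. A list's median was placed among 10000 random lists of the same size, drawn from the 40 miRNAs nearest to each member in mean signal, as a description of these arrays. The groups, comparisons, lists, rule for names and all alternatives except spike scaling were fixed before the data were examined.

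On simulated data, 20 sets of 4 arrays were drawn from the mean signals with technical noise, with 10 miRNAs changed 2-fold and 10 changed 4-fold by irradiation in both genotypes. The limma fit recovered 79.0% of the 2-fold and 97.5% of the 4-fold changes, with a mean of 3.75 false calls per set among 780.2 miRNAs tested. For the ratio of 1 pair of arrays, the 2-fold count recovered 6.5% and 92.0%, with 0 false calls. In the limma fit, the offset reduced the median log2 change of all changed miRNAs to 0.672 and 1.54. These simulations hold no spread between pools.

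Alternatives were scaling to the median of probes detected on all arrays, scaling to the 75th percentile, cyclic loess, the authors' values, an offset of 16, no background correction, subtraction of the blank mean, no detection filter, a filter at 3 times the threshold, and size limits of 1.5-fold and 3-fold. For the averaged fits they were also 1 term in place of 2, an intensity trend, detection on all arrays, and leaving out each array with 1 term fitted. Scaling to the spike controls was added after seeing the data. Gene neighbours were looked up in a RefSeq gene table of assembly GRCm38.p6, and no coordinates are given. Probe sequences were not analysed here. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.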

Results

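MicroRNA levels were measured in the small intestine of Tlr3+/+ and Tlr3-/- mice, either not treated (0 hr) or 6 hr after total body gamma-irradiation with 10 Gy. TLR3 is a Toll-like receptor that senses double-stranded RNA, and the labels set mice that lack it against mice that carry it. The 4 groups had 1 array each, and each array held RNA pooled from 3 mice, so no group had replicates and the number of arrays limits the precision of every value. As the deposited names read, the non-treated arrays shared 1 slide and the irradiated arrays lay on 2 others, so slide and irradiation cannot be told apart, and neither can slide and genotype at 6 hr or in the difference of the irradiation ratios. No array held non-treated intestine at 6 hr, so irradiation and time cannot be told apart either. The array measures miRNAs and not Tlr3 mRNA, so the genotype labels could not be checked from these values. Of 1096 mouse miRNA probes, 779 were detected in Tlr3+/+ at 0 hr, 721 in Tlr3-/- at 0 hr, 778 in Tlr3+/+ at 6 hr and 711 in Tlr3-/- at 6 hr, and 573 were detected on all 4 arrays. Blank spots averaged a raw intensity of 24.5, 24.9, 24.7 and 27.3 on these arrays in the same order, and the brightest miRNA read 8182, 7256, 7193 and 7057. The highest mean of a negative control was 26.2, 26.7, 27.5 and 29.7, above the detection threshold of each array. Other negative controls lay below it on some arrays. A detected call near the threshold therefore does not show that a miRNA was present. The highest signals in non-treated Tlr3+/+ intestine included miR-3968 at 8182, and miR-194 at 5941, miR-215 at 5461 and miR-192 at 2224, which are abundant in intestinal epithelium. Names are given without the species prefix, an asterisk marks the star strand as the array names it, and log2 ratios were computed from normalized intensities.

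The first comparison asked how irradiation altered miRNA levels in intestine with TLR3. At 6 hr, 12 of the 680 miRNAs detected on both Tlr3+/+ arrays were at least 2-fold higher than at 0 hr and 0 were at least 2-fold lower. The highest ratio was that of miR-92b*, 4.17-fold (log2 2.06), with raw intensities of 128 and 705. It was followed by miR-2861 at 3.36-fold, miR-326* at 3.27-fold, miR-2137 at 2.75-fold and miR-5126 at 2.33-fold. On the low side, miR-21, a miRNA linked to growth and inflammation, had a log2 ratio of -0.88. miR-143, abundant in smooth muscle, had -0.80, against -0.35 to -0.14 in 5 other scalings.

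The remaining miRNAs of the 12 were miR-3473 (log2 1.20), miR-762 (1.20), miR-3102* (1.16), miR-451 (1.11), miR-3090* (1.05), miR-3077* (1.04) and miR-5128 (1.02), the last of which passed 2-fold in 1 of 5 other scalings where the others passed in all 5. miR-451 is abundant in red cells, and its ratio started from a raw intensity of 42.3 at 0 hr. Other low ratios were those of miR-1927 (-0.75), miR-5112 (-0.55), miR-5099 (-0.54), miR-203 (-0.54), let-7b (-0.53) and miR-16 (-0.53). miR-192 stood at -0.57, against -0.23 to -0.03 in the other scalings. miR-720 stood at -0.52 but changed sign in 3 of 5 other scalings. Of the 10 lowest, 6 were nearer to 0 in every other scaling, among them let-7b (-0.40 to -0.19), miR-16 (-0.40 to -0.18) and miR-21 (-0.80 to -0.58), against 0 of the 10 highest. Of all compared miRNAs, 87.1% lay within 0.25 of 0 on the log2 scale.

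Among the fixed lists, all 11 measured leukocyte miRNAs had ratios below 0 in Tlr3+/+ intestine. Their median was -0.21 (-0.53 to -0.09 in other scalings), at percentile 0.84 of 10000 random lists of matched signal. The members included miR-142-5p at -0.37, miR-146a at -0.27, miR-150 at -0.23 and miR-223 at -0.22. None was 2-fold lower. The probes of miR-342-3p at -0.07, miR-155 at -0.06 and miR-155* at -0.02 were dim, and the offset shrinks such ratios. In the authors' values these 3 had -0.21, -0.86 and -0.65. The 12 measured let-7 members were all below 0 (median -0.21, percentile 8.92), as were the 8 of the miR-30 family (median -0.18, percentile 21.0). Random lists of matched signal had a median of -0.12 for each. All 104 miRNAs above 3 times the detection threshold on both arrays had a median of -0.20, so bright miRNAs in general lay below 0. In the miR-17~92 list, which holds clusters linked to proliferation, 15 of 19 members were below 0 (median -0.15, percentile 5.48, -0.33 to -0.01 in other scalings). The innate immunity list stood at -0.06 (percentile 4.62) with miR-155 at -0.06, and the DNA damage list at -0.06 (percentile 12.4). The p53-responsive list had a median of -0.04 (percentile 28.0), and miR-34a, a direct target of p53, was at -0.04. Epithelial miRNAs had a median of -0.08 (percentile 43.0), smooth muscle and stroma -0.12 (percentile 29.1), miR-15/16 -0.18 (percentile 12.4) and miR-29 -0.18 (percentile 21.1). The neuron list had -0.02 (percentile 16.7). Striated muscle had 0.02 (percentile 78.2) and pancreas and liver -0.10 (percentile 18.7), and these 2 medians changed sign in at least 1 of 5 other scalings. Of the red cell list only miR-451 and miR-486* were detected on both arrays, at 1.11 and 0.50. No test within Tlr3+/+ was possible with 1 array per condition. The authors' normalized values, which do not damp dim probes, gave 48 miRNAs at least 2-fold higher and 25 at least 2-fold lower.

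**Figure D1:**
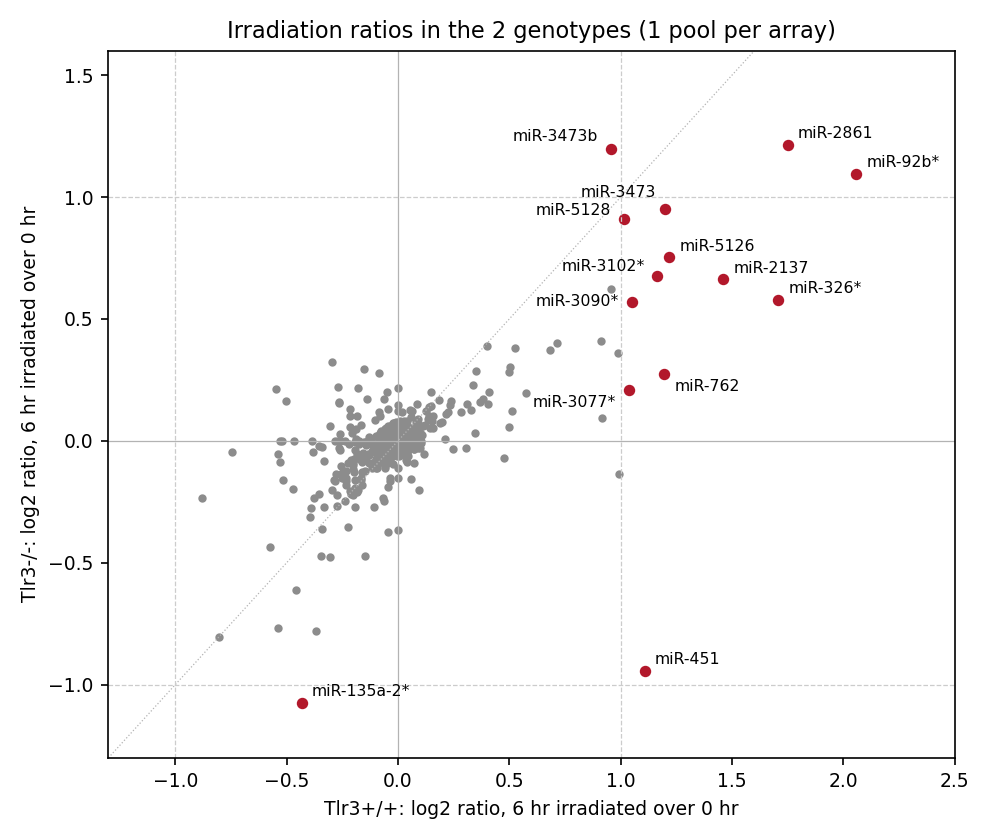
Log2 ratio of irradiated (6 hr) over non-treated (0 hr) signal in Tlr3+/+ intestine (x axis) against the same ratio in Tlr3-/- intestine (y axis), one point for each of 573 miRNAs detected on all 4 arrays, with dashed lines at 2-fold and named points (red) at or beyond 2-fold in at least 1 genotype. miR-2861 and miR-92b* lie beyond 2-fold on both axes, and miR-451 lies at 1.11 on the x axis and -0.94 on the y axis.

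The same question was put to intestine without TLR3. In Tlr3-/- mice, 3 of 625 miRNAs were at least 2-fold higher at 6 hr than at 0 hr: miR-2861 at 2.32-fold, miR-3473b at 2.29-fold and miR-92b* at 2.14-fold. The only miRNA at least 2-fold lower was miR-135a-2*, with a log2 ratio of -1.07 and raw intensities that went from 86.6 to 30.4, close to the detection threshold of 29.2. miR-451 had a ratio of -0.94 and miR-142-5p, a miRNA of blood cells, -0.78. miR-143 had -0.80, against -0.51 to -0.20 in 5 other scalings.

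Further high ratios in Tlr3-/- intestine were those of miR-3473 (0.95), miR-5128 (0.91), miR-5126 (0.75), miR-3102* (0.68), miR-2137 (0.66), miR-5122 (0.62) and miR-326* (0.58). Further low ratios were miR-5099 at -0.77, miR-709 at -0.61 (-0.42 to -0.11 in other scalings), miR-29b at -0.48, miR-10a at -0.47 and miR-128-2* at -0.47. miR-192 was at -0.43 and changed sign in 3 of 5 other scalings. Of the 10 lowest, 4 were nearer to 0 in every other scaling, among them miR-29b (-0.46 to -0.13), against 0 of the 10 highest. Of the leukocyte list, 8 of 10 measured members were below 0 (median -0.13, percentile 0.32), with miR-146a at -0.22 and miR-150 at -0.16. Smooth muscle and stroma miRNAs had a median of -0.09 (percentile 1.12). Scaled to the spike controls, these leukocyte and smooth muscle medians turned to 0.03 and 0.12. The innate immunity list had -0.04 (percentile 3.53) and the let-7 list -0.01 (percentile 47.0), and both also changed sign in at least 1 of 5 other scalings. The p53-responsive list had a median of 0.00 (percentile 46.2) and the epithelial list 0.00 (percentile 69.7). The dim miR-34a was at 0.13, and at 0.65 in the authors' values. The authors' values gave 18 miRNAs at least 2-fold higher and 20 at least 2-fold lower, and spike scaling 7 higher and 0 lower.

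Responses in the 2 genotypes were set side by side over the 573 miRNAs detected on all 4 arrays. miR-2861 and miR-92b* were at least 2-fold higher in both, where 0.063 would be shared by independent lists of 12 and 3. In all 5 other scalings miR-3473 and miR-3473b also passed 2-fold in both genotypes. At 1.5-fold, 20 miRNAs were higher in Tlr3+/+ and 9 in Tlr3-/-, and all 9 were among the 20: miR-2137, miR-2861, miR-3102*, miR-3473, miR-3473b, miR-5122, miR-5126, miR-5128 and miR-92b* (0.314 for independent lists). In Tlr3-/- miR-5122 passed 1.5-fold in 2 of 5 other scalings, where the rest of the 9 passed in all 5. On the low side at 1.5-fold, 3 and 6 miRNAs shared miR-143, which passed 1.5-fold in 0 of 5 other scalings in either genotype. Of the 12 miRNAs 2-fold higher in Tlr3+/+, 11 were above 0 in Tlr3-/-, with a median of 0.67, and the exception was miR-451. Across miRNAs, which are not independent replicates, the log2 ratios of the genotypes had a Pearson r of 0.68 and a Spearman rho of 0.50. No array entered both ratios, but the non-treated arrays of both shared 1 slide name and all 4 arrays were normalized together. The ratios are therefore not fully independent, and slide and irradiation cannot be told apart in their agreement.

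**Figure D2:**
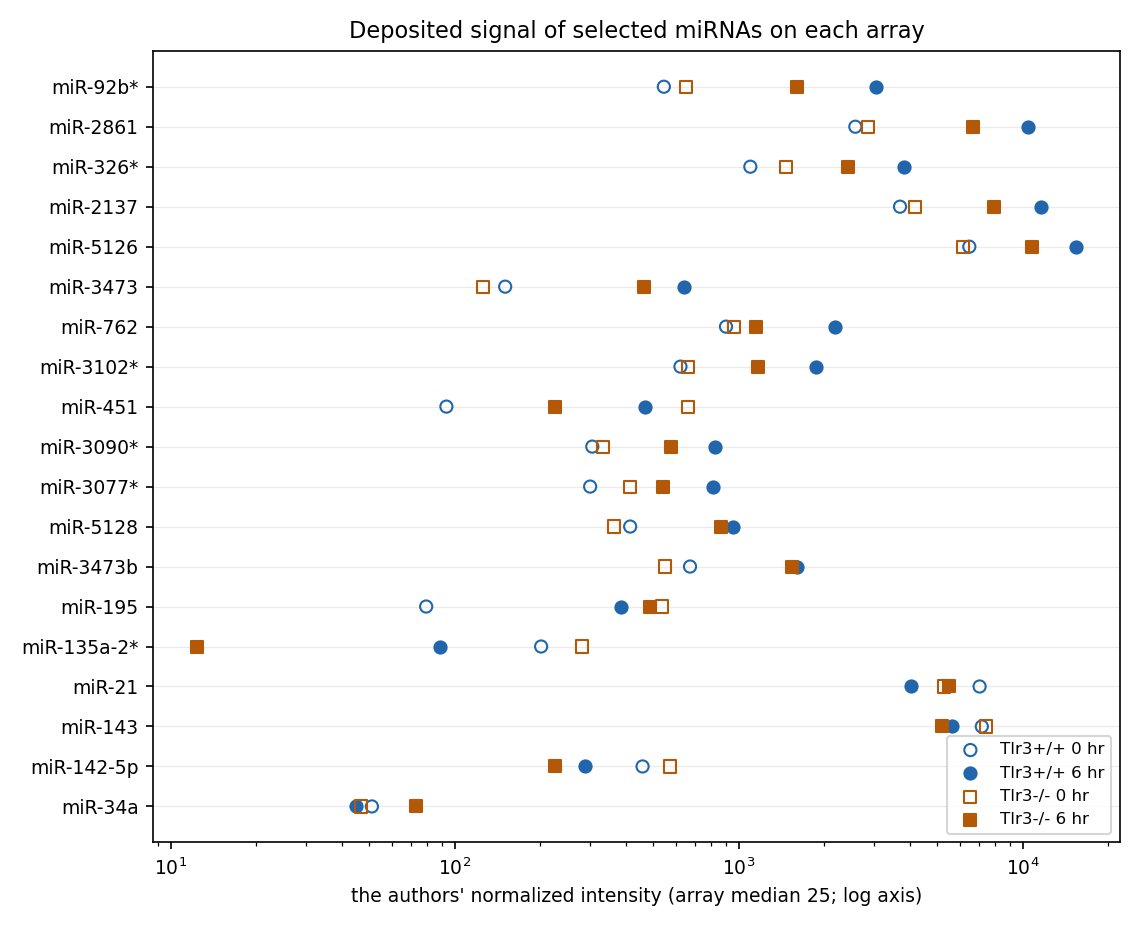
The authors' normalized intensity (log axis, scaled by the authors to a median of 25 per array) of selected miRNAs on each of the 4 arrays, 1 pool of 3 mice per array, open symbols for 0 hr and filled symbols for 6 hr. miR-92b* reads 545 and 3038 in Tlr3+/+ and 654 and 1610 in Tlr3-/-, while miR-451 at 93.5 and miR-195 at 79.3 have their lowest value on the non-treated Tlr3+/+ array.

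Non-treated intestine of the genotypes was compared to find miRNAs that differ without irradiation. In Tlr3-/- intestine at 0 hr, 2 of 656 miRNAs were at least 2-fold higher than in Tlr3+/+ and 0 were at least 2-fold lower. These were miR-451 at 2.94-fold, with raw intensities of 42.3 in Tlr3+/+ and 171 in Tlr3-/-, and miR-195 at 2.50-fold, with 39.6 and 143 (and 111 and 146 at 6 hr). The miRNA miR-497, whose gene lies 241 bp from that of miR-195 in the mouse reference assembly GRCm38.p6, had a ratio of -0.13. The next highest were miR-326* (0.60, and 0.27 to 0.53 in other scalings), miR-2137 (0.46), miR-3077* (0.45), miR-10a (0.39), miR-211* (0.36), let-7g (0.34), miR-142-5p (0.34) and miR-30c (0.31). These depended on the scaling: miR-2137 had 0.10 to 0.36 in the others, let-7g 0.013 to 0.28, miR-30c 0.039 to 0.30 and miR-142-5p 0.10 to 0.36. Of the 10 highest, all but miR-451 and miR-195 were less than their value divided by 1.5 in at least 1 other scaling.

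The lowest ratios at 0 hr were miR-5112 at -0.63, miR-1927 at -0.62, miR-141, an epithelial miRNA of the miR-200 family, at -0.61 and miR-24 at -0.37. They were followed by let-7c (-0.32), miR-17 (-0.30), miR-494 (-0.29), miR-20b (-0.29) and miR-151-5p (-0.29), and by miR-200c (-0.29), which changed sign in 2 of 5 other scalings. Of these 10, 6 were less than their size divided by 1.5 in at least 1 other scaling. Of the leukocyte list, 9 of 12 members were above 0 in Tlr3-/- (median 0.09, percentile 100). The neuron list had a median of 0.04 (percentile 99.5). Its compared probes read 26.3 to 33.2 on these arrays, near the detection thresholds of 25.8 and 26.5. Under spike scaling these 2 medians turned, to -0.14 for leukocyte and -0.22 for neuron. The miR-17~92 list had -0.05 (percentile 3.96), with -0.30 to -0.01 in other scalings, the epithelial list had -0.01 (percentile 19.1), with -0.26 to 0.00 in other scalings, and the p53-responsive list had 0.00 (percentile 43.0). Of all compared miRNAs, 95.7% lay within 0.25 of 0. Neither miR-451 nor miR-195 was above 3 times the detection threshold on both arrays, so that filter left 0 miRNAs at 2-fold, and the authors' values gave 7 higher and 18 lower.

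Irradiated intestine of the genotypes was then compared. At 6 hr, 0 of 645 miRNAs differed by 2-fold or more between Tlr3-/- and Tlr3+/+. The lowest ratios in Tlr3-/- were those of miR-762 (-0.83), miR-92b* (-0.73), miR-494 (-0.69), miR-149* (-0.55), miR-326* (-0.53) and miR-451 (-0.49), and miR-762, miR-92b* and miR-494 passed 1.5-fold (in 5, 5 and 3 of 5 other scalings). The highest were miR-26a (0.56), miR-720 (0.52), miR-690 (0.46, and 0.05 to 0.23 in other scalings), let-7b (0.42), miR-29a (0.37) and miR-21 (0.37).

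The low side went on with miR-5126 (-0.46), miR-211* (-0.46), miR-3077* (-0.38) and miR-328* (-0.37), and the high side with miR-145 (0.33), let-7g (0.33), miR-203 (0.31) and let-7c (0.29). Of the 10 highest, 5 were nearer to 0 in every other scaling, among them miR-720 (0.21 to 0.38) and miR-145 (0.09 to 0.26), and of the 10 lowest 1, miR-328* (-0.31 to -0.14). Several lists had medians above 0 in irradiated Tlr3-/- intestine, whose array lay on another slide than that of irradiated Tlr3+/+. The miR-30 family had 8 of 8 members above 0 (median 0.17, percentile 99.7) and the miR-15/16 family 7 of 7 (median 0.20, percentile 99.8). Leukocyte miRNAs had 8 of 10 above 0 (median 0.13, percentile 99.3), let-7 had 10 of 12 (0.14, percentile 98.3), and the DNA damage list 14 of 17 (0.08, percentile 99.8). The p53-responsive list had 12 of 16 (0.09, percentile 99.5) and the epithelial list 16 of 19 (0.10, percentile 99.0). In 5 other scalings these 7 medians stayed above 0, but the lowest values were 0.008 for the p53-responsive list, 0.011 for DNA damage, 0.020 for epithelium and 0.022 for leukocyte. The lowest for let-7 was 0.07, for miR-30 0.13 and for miR-15/16 0.17, and members overlap between some lists. The red cell list, with 3 members, had -0.19 (percentile 2.28). No miRNA of any list reached 2-fold, and miR-34a was at 0.19 (0.70 in the authors' values). The authors' values gave 14 miRNAs at least 2-fold higher and 29 at least 2-fold lower.

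**Figure D3:**
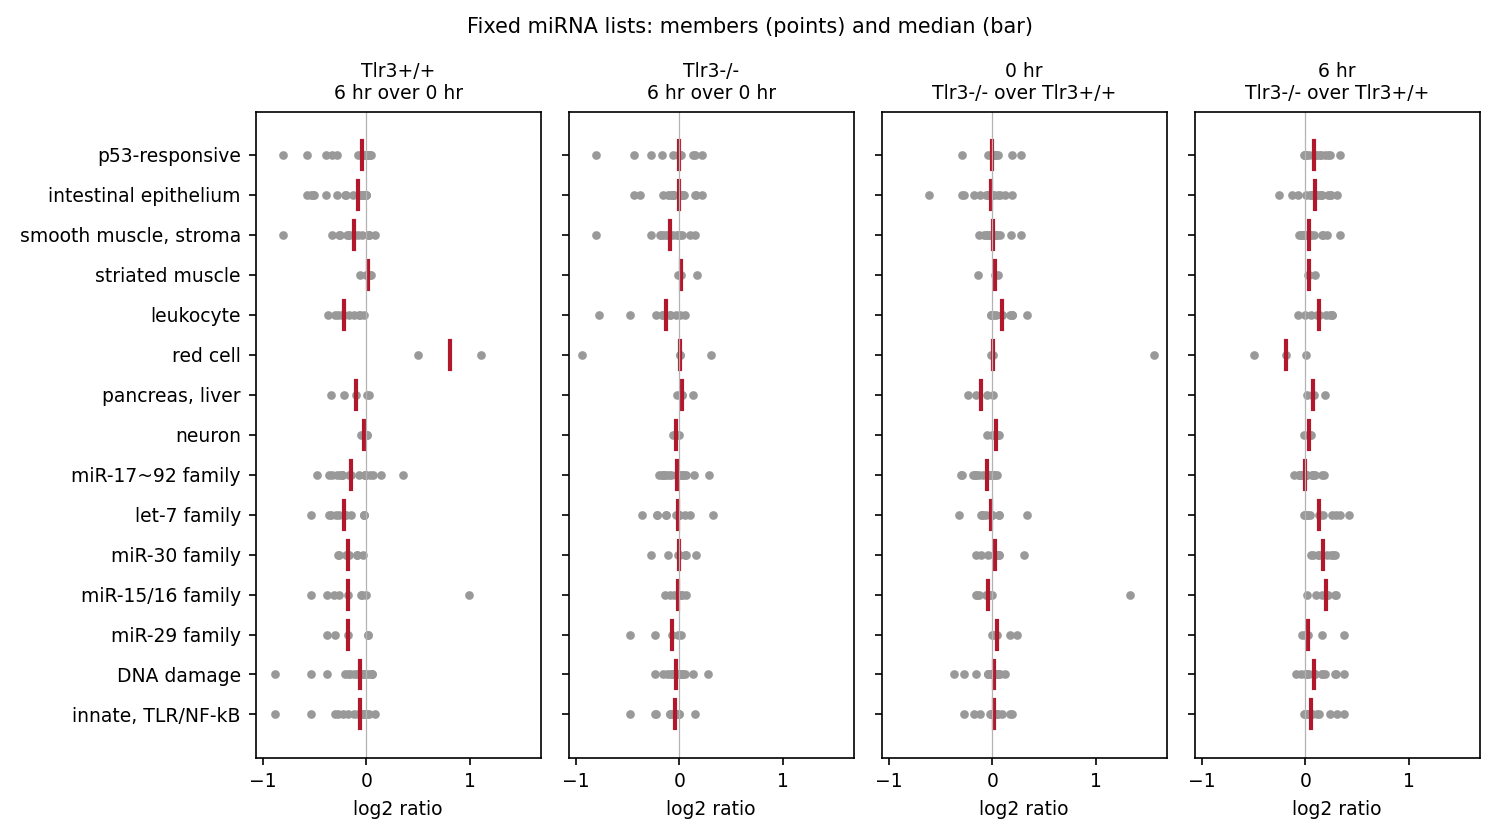
Log2 ratios of the measured members (grey points) of 15 fixed miRNA lists and the list median (red bar) in each of the 4 comparisons, with the ratio's direction above each panel. The leukocyte median lies at -0.21 and -0.13 in the irradiation panels, where the second turned to 0.03 under spike scaling, and at 0.13 between the irradiated genotypes, where other scalings gave 0.022 to 0.19.

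The difference of the irradiation ratios, Tlr3-/- minus Tlr3+/+, asked whether the response depended on TLR3. Of 573 miRNAs, 3 had a difference at or below -1 and 0 at or above 1. These were miR-451 at -2.05, miR-326* at -1.13 and miR-195 at -1.13, followed by miR-92b* at -0.96 and miR-762 at -0.92. In 5 other scalings miR-451 was at or below -1 in all 5, miR-195 in 4, miR-326* in 1 and miR-92b* in 4. The highest differences were miR-5112 (0.76), miR-1927 (0.70), miR-141 (0.67), miR-21 (0.65) and let-7c (0.62). For miR-195 the difference came from the non-treated arrays, since its irradiated signals differed by 0.20 between the genotypes. The miR-15/16 list had a median of 0.29 (percentile 99.3) and the epithelial list 0.13 (percentile 98.9), with lowest values of 0.08 for each in other scalings. DNA damage had 0.08 (percentile 98.8, lowest 0.05) and pancreas and liver, with 4 members, 0.22 (percentile 98.4, lowest 0.07). The red cell list, of miR-451 and miR-486* only, had -1.12 (percentile 0). Selected on the average of both genotypes, 15 miRNAs were at least 1.5-fold higher after irradiation, and 14 of them had the larger ratio in Tlr3+/+, with medians of 1.16 in Tlr3+/+ and 0.66 in Tlr3-/-. The 3 selected as lower, miR-135a-2*, miR-143 and miR-5099, had medians of -0.54 in Tlr3+/+ and -0.80 in Tlr3-/-, and 0 of them had the larger change in Tlr3+/+ (miR-143 was equal in both). No difference was tested, since each cell of the design held 1 array. The authors' values gave 32 differences at or above 1 and 33 at or below -1, and spike scaling gave 0 and 1.

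A fit averaged over both genotypes asked which miRNAs moved with irradiation in both. With limma, 0 of 797 miRNAs passed an adjusted p of 0.05 for irradiation, and 100 had an unadjusted p under 0.05. The lowest adjusted p, 0.131, was that of miR-143 (log2 change -0.80). Quantile normalization gave miR-143 equal values in both genotypes at each time, which sets the disagreement behind this p to 0. In 5 other scalings its change was -0.43 to -0.17 and its adjusted p 0.254 to 0.965. For miR-3473b and miR-3473 the changes were 1.08 and 1.07, each at an adjusted p of 0.222 and higher in both genotypes. For genotype, averaged over irradiation, 0 of 797 passed and 38 had an unadjusted p under 0.05, with let-7g lowest at an adjusted p of 0.629 and a log2 change of 0.33. These 4 miRNAs were singled out after their values were seen. In this fit the spread is the disagreement between the genotypes and not a spread between pools. Scaling to the spike controls gave 35 miRNAs for irradiation, 32 of them higher, and 3 for genotype. Under it eBayes gave all miRNAs 1 common spread, unlike under the other settings, so these counts cannot be set beside the others. For irradiation, 54 miRNAs had an unadjusted p under 0.05 with spike scaling, against the 100 above.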

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

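All tests in this part were chosen after the results were seen. miR-451 stood out because its irradiation ratio was positive in Tlr3+/+ (1.11) and negative in Tlr3-/- (-0.94), a difference of -2.05 that was not tested, since each genotype had 1 array per condition. The raw intensity of a probe for the mouse cytomegalovirus miRNA mcmv-miR-M23-1-3p, outside the mouse comparisons, was 43.3 in irradiated Tlr3+/+ intestine, against 24.9 in non-treated Tlr3+/+, below that array's detection threshold of 25.8. In Tlr3-/- it was 27.1 at 0 hr and 32.5 after irradiation.

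The first pattern is the set of 12 miRNAs at least 2-fold higher after irradiation in Tlr3+/+. Spot defects on the Tlr3+/+ arrays are opposed as the whole cause, since on the other pair of arrays the same 12 had a median log2 ratio of 0.67 and 11 were above 0. For scaling between arrays, the lowest median of the 12 over 5 other scalings was 1.28, so the choice among these scalings did not make the set. Those scalings left the median of all compared miRNAs between -0.145 and -0.0068. They had little room to lower ratios selected at 2-fold, so this value cannot decide on scaling as a cause. Slide stays open: as the deposited names read, the non-treated arrays shared 1 slide and the irradiated arrays lay on 2 others, and 0 slides held both conditions, so slide and irradiation cannot be told apart. A response of the intestine to irradiation, the biological difference in the design, remains a hypothesis that may hold beside the slide.

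The second pattern is miR-451 differing between the 4 arrays, from a raw intensity of 42.3 in Tlr3+/+ to 171 in Tlr3-/- without treatment, and 129 and 82.7 after irradiation. A single defective spot is opposed, since with any 1 array left out the other 3 still spanned at least 0.94 on the log2 scale. A different content of red cells may account for it. Yet among the probes of miR-144, miR-144*, miR-486 and miR-486* the highest log2 ratio between genotypes at 0 hr was 0.068. That value is of the miR-486 probe, which also names miR-3107. miR-486*, at raw intensities of 38.5 and 40.3 there, had 0.01, and with irradiation in Tlr3-/- it had 0.30 where miR-451 had -0.94. These values go against that explanation. In Tlr3+/+, however, miR-486* rose with miR-451 after irradiation, at 0.50 and 1.11, as red cell content would give. As miR-486* was dim and the other red cell probes lay nearer still to the blanks, red cell content and a change of miR-451 itself cannot be told apart. Genotype and irradiation were not tested as causes.

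The third pattern is miR-195, low in non-treated Tlr3+/+ at a raw intensity of 39.6 and between 111 and 146 on the other arrays. With that array left out, the others spanned 0.33 on the log2 scale. This span restates the pattern, so it cannot decide on a single defective spot, which remains a candidate explanation. Transcription of the shared cluster of miR-195 and miR-497 is opposed, since miR-497 had a log2 ratio of -0.13 between the non-treated genotypes, where miR-195 had 1.32. A difference in miR-195 processing or stability in the pool was not tested.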

How the results depend on the processing

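Scaling to the spike controls was chosen after seeing the data. Counts at 2-fold were within 1.5 times under median, 75th percentile and cyclic loess scaling in all 5 comparisons, though the miRNAs counted can differ. With no detection filter they were unchanged. Under the other settings some moved by more, as given here, and the cause was not tested except where the setting changes the size limit or the signal filter. With the authors' values the counts were 73 for irradiation in Tlr3+/+ (12 in the report), 38 in Tlr3-/- (4), 25 between genotypes at 0 hr (2), 43 at 6 hr (0) and 65 for the difference of ratios (3). Subtracting the blank mean gave 69, 40, 22, 30 and 65 in that order. An offset of 16 gave 19 in Tlr3+/+, 8 in Tlr3-/- and 9 for the difference, and no background correction gave 7 in Tlr3-/- and 5 for the difference. Spike scaling gave 7 in Tlr3-/- and 1 for the difference. The filter at 3 times the threshold left 0 at 0 hr and 1 for the difference. At 1.5-fold the counts were 23, 15, 6, 3 and 15, and at 3-fold they were 3 in Tlr3+/+, 0 in Tlr3-/-, 0 at 0 hr and 1 for the difference. In the limma fit averaged over genotypes, irradiation gave 1 miRNA under median scaling, 1 under the 75th percentile, 1 under cyclic loess, 35 under spike scaling and 3 without the genotype term, against 0. Genotype gave 3 under spike scaling against 0. The spike-scaled fits gave all miRNAs 1 common spread, unlike the other fits. Leaving out each array in turn also dropped the second term, assumed the lone array of a condition to vary like the others, and gave 0 in each of 8 fits. The 1-term fits of all 4 arrays gave 3 for irradiation and 0 for genotype.

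Of 75 list medians, 27 changed sign under spike scaling, 11 with the authors' values, 10 under median, 9 under 75th percentile and 6 under cyclic loess scaling. Among medians in the outer 2.5 percentiles of matched random lists on either side, 4 changed sign, all under spike scaling: smooth muscle and stroma to 0.12 and leukocyte to 0.031 for irradiation in Tlr3-/-, and leukocyte to -0.14 and neuron to -0.22 between genotypes at 0 hr. Under it the median of all compared miRNAs was -0.25 at 0 hr, 0.15 for irradiation in Tlr3-/- and 0.17 for the difference, against 0.00, 0.00 and 0.01 in the report's scaling. Both of the turned Tlr3-/- irradiation medians lie below that 0.15, and both of those at 0 hr lie above that -0.25. With the authors' values the median of all was -0.15 for irradiation in Tlr3+/+ (-0.01 in the report's scaling) and -0.17 at 0 hr, and with blank subtraction -0.12 for irradiation in Tlr3+/+. The next counts run over all settings and take each value under each setting as a separate case. For list medians, 554 cases stayed within the technical spread, 177 moved beyond it and 4 were classed as reversed. For named miRNAs, 362 cases stayed and 358 moved. The technical spread is that of bright spike spots, while the offset shrinks ratios of dim probes. Staying within that spread therefore does not show that a list median is independent of the setting. Of the 15 miRNAs higher on average, 13 or 14 had the larger ratio in Tlr3+/+ in each of 8 other settings, and of the 3 lower on average 0 had the larger change in Tlr3+/+. Signal over background limits dim miRNAs most: the median raw intensity of detected probes was 29.3 to 33.4, against blank means of 24.5 to 27.3.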

Other observations

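All values in this part were singled out after the data were seen. Of the 12 miRNAs at least 2-fold higher after irradiation in Tlr3+/+ intestine, 5 are named as star strands: miR-92b*, miR-326*, miR-3102*, miR-3090* and miR-3077*. Star strands made up 193 of the 680 compared miRNAs and 12 of the 104 above 3 times the detection threshold on both arrays. The opposite strands were dim, at most at a raw intensity of 42.8 on these arrays, and had log2 ratios from -0.08 for miR-92b, with 42.1 and 42.8, to 0.08 for miR-3102, with 28.9 and 33.3. miR-326 was at -0.01, miR-3090 at -0.01 and miR-3077 at -0.04. The difference between strands was not tested.

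The main miRNAs of intestinal epithelium stayed bright in every group. miR-194 had raw intensities of 5941 in Tlr3+/+ and 6969 in Tlr3-/- at 0 hr, and 5822 and 7057 at 6 hr. miR-215 had 5461, 5443, 5412 and 6788 on the arrays of Tlr3+/+ and Tlr3-/- at 0 hr and of Tlr3+/+ and Tlr3-/- at 6 hr. miR-34a stayed dim, at 34.2, 35.1, 34.7 and 45.2 in the same order, with log2 ratios for irradiation of -0.04 and 0.13. In the authors' values, without the offset, these ratios were -0.18 in Tlr3+/+ and 0.65 in Tlr3-/-. There the ratio between genotypes at 6 hr was 0.70. The small ratios with the offset therefore do not show that miR-34a was unchanged.

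Many miRNAs were detected on only 1 array of a pair: 197 for irradiation in Tlr3+/+, 182 in Tlr3-/-, 188 between genotypes at 0 hr and 199 at 6 hr. In the values with the offset, which shrinks ratios of dim probes, none had a ratio of at least 1.5-fold against the lowest detected signal of the other array. The highest bound of each comparison, as the log2 excess of the brighter array, was 0.10 for miR-1901 (irradiation in Tlr3+/+, higher at 6 hr) and 0.22 for miR-146b* (irradiation in Tlr3-/-, higher at 0 hr). Between genotypes it was 0.23 for miR-146b* at 0 hr and 0.10 for miR-455* at 6 hr, both higher in Tlr3-/-. In the authors' normalized values, without the offset, miR-146b* read 41.9 in Tlr3-/- at 0 hr. It was not detected in Tlr3+/+ at 0 hr, where the detected miR-216b* read 6.65. These small bounds therefore depend on the offset and do not show that large changes were absent among such miRNAs.

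Of the 39 viral probes, 13 were detected on all 4 arrays and 5 on none. A single probe, mcmv-miR-M23-1-5p, was above 3 times the detection threshold on all 4 arrays, at raw intensities of 241, 207, 225 and 250.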
